A study of Homo sapiens with 21 samples.

How the data were processed

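RNA from 21 samples of NCRM1, a human induced pluripotent stem cell line, had been taken during differentiation towards paraxial mesoderm, the tissue that forms the somites, in a stem-cell-derived model of segmentation. Per the labels, RNA was purified with a column kit and a polyA-selected library was made and sequenced for each sample. The labels put the samples into 7 groups of 3: unsorted cells at 48 h, 66 h and 120 h, sorted fractions with high and low MESP2 at 72 h, and sorted fractions enriched for MESP2 and for UNCX at 120 h. The labels give the genotype as wild type and describe no reporter by which the sort read MESP2 or UNCX. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

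The submitters' processing notes name FastQC 0.11.9, Salmon 1.4.0, STAR 2.7.6a and DESeq2 and the genome build GRCh38, with no role, order or annotation release. Each deposited table holds Salmon estimated counts for 178398 transcripts, which need not be whole numbers and are not normalized between samples. The deposited tables also list for each transcript an effective length, a unit outside the usual expression units (other), which was used here only for an alternative fit, and TPM values, which were not used here. Whether the quantification used strand is not given in the sources used here, so values of genes that overlap on opposite strands, such as KRT8 and KRT18, are uncertain to that extent.

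Transcript identifiers were matched without their version to the GENCODE 29 annotation of GRCh38. Of the 178398 transcripts, 167049 matched and their estimated counts were summed into 35106 genes and rounded to whole numbers. The other 11349 transcripts held 2.57 to 3.02% of each library's reads and took no part in tests or library sizes. Some of them belong to alternative copies of chromosome regions, so the levels of HSPA1A, HSPA1B, IER3 and genes of the major histocompatibility complex are uncertain. Library totals ran from 15685113 to 38250175 reads.

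The tests used edgeR 4.0.16 in R 4.3.3. Low-count genes were removed with filterByExpr, which left 17024 genes, libraries were scaled by TMM, and all 21 libraries entered 1 quasi-likelihood fit with a coefficient per group, so that the groups share an estimate of the spread (prior degrees of freedom 3.68). Changes are log2 fold changes at edgeR's default prior count. Their standard error (SE) is the size of the change divided by the square root of its F value. A prior count of 2 was set only for log2 CPM values. P-values were adjusted by Benjamini-Hochberg within a comparison and genes with an adjusted p under 0.05 were called. Levels are CPM (counts relative to the TMM-scaled library size), given as the mean ± SD of 3 libraries unless stated. No fold is given where a group held fewer than 10 reads of a gene. The comparisons were 66 h against 48 h, 120 h against 66 h, high against low MESP2 at 72 h, the MESP2 fraction against the UNCX fraction at 120 h, the mean of those fractions against unsorted cells at 120 h, and the difference between the fraction differences at 72 h and 120 h.

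Before the data were examined, 33 lists of genes were fixed, with 407 genes of which 367 were tested. They cover stages of paraxial mesoderm, signalling pathways, cell processes and markers of other cell types. Each was tested against all other genes with limma 3.58.1's camera at a preset correlation of 0.01 and again with an estimated correlation, with p-values adjusted over the lists of a comparison. The genes named are MESP2 and UNCX, the 8 protein-coding genes with the largest and the 8 with the smallest change among called genes of each comparison, and up to 4 called members of each list by size of change. The 8 were ranked on levels with 1 CPM added, among genes at 5 CPM or more in the higher group and, except for the difference of differences, with no overlap between the groups' libraries. The same ranking gave the 8 genes named as highest at 66 h. Part of the genes that these rules select are described, and 1 of the others was withheld and is not reported here. Principal components were computed on 11594 genes with a mean log2 CPM above 2.

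On simulated counts with seeded genes changed 2-fold or 4-fold, 193 to 200 of which were tested, the fit for 66 h against 48 h recovered 56.7% of 2-fold and 84.7% of 4-fold changes over 16687 genes. For 120 h against 66 h the shares were 71% and 85.6% over 16697 genes, and for the fractions at 72 h they were 68% and 81.2% over 16696 genes. For the fractions at 120 h they were 66% and 86.9% over 16726 genes, for sorted against unsorted cells 66% and 78% over 16697 genes, and for the difference of the fraction differences 53.1% and 71.1% over 16666 genes. False calls made up 2.8 to 6.7% of calls. The simulated counts were drawn independently around each gene's mean over all libraries. They hold no outlying libraries and no deviations shared between libraries, so these shares need not hold for the real libraries.

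Replicates of a group differed by more than sampling noise: the chi-square per gene between replicates was 8.35 at the lowest and 70.51 at the highest. The labels give the groups shared replicate numbers. Deviations from the group means correlated between same-numbered libraries at 0.465, 0.414 and 0.635 for 48 h and 66 h, at 0.33, 0.248 and 0.626 for 66 h and 120 h, at 0.245, 0.179 and 0.555 for the fractions at 72 h, and at 0.363, 0.545 and 0.177 for the fractions at 120 h. Each of these values is over 0.1, so the numbers were read as pairing the samples of these comparisons, from the data and not from a stated batch. Replicates 1 and 2 with different numbers correlated as well, at 0.282 and 0.347 for 48 h and 66 h, 0.462 and 0.406 for 66 h and 120 h, and 0.272 and 0.38 for the fractions at 72 h, so in these 3 comparisons the values mainly set replicate 3 apart. Between unsorted and sorted cells at 120 h the values were −0.287 to 0.221, so those samples share only a number. The labels give no batch.

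The alternatives fixed before the data were examined were no count filter, a stricter count filter, DESeq2 1.42.0 size factors, the DESeq2 test, an offset for transcript length, a fit of only the libraries compared, a fit with the replicate number as a block, and leaving out each library in turn. Another 3 were chosen after seeing the data: leaving out 4 sorted libraries that hold keratinocyte transcripts, leaving out replicate 3 of the unsorted groups, and a replicate block within each set of libraries (unsorted, 72 h fractions, 120 h fractions).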

Results

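Gene expression was measured by RNA sequencing in NCRM1, a human induced pluripotent stem cell line, as the cells were driven towards paraxial mesoderm and somites in culture. The 21 libraries form 7 groups of 3. Unsorted cells were taken at 48 h, 66 h and 120 h. Cells sorted into fractions with high and low MESP2 were taken at 72 h, and fractions enriched for MESP2 and for UNCX were taken at 120 h. MESP2 is a basic helix-loop-helix factor switched on in the anterior presomitic mesoderm, where the next somite boundary will form, and it marks the future rostral part of a somite. UNCX is a homeobox factor of the caudal part of the somite.

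The unsorted libraries held 27668896 to 36585220 reads at 48 h, 20446724 to 35508039 at 66 h and 26281140 to 38250175 at 120 h. The 72 h fractions held 19311332 to 37087225 reads (high MESP2) and 21120275 to 36918971 (low MESP2), and the 120 h fractions held 15685113 to 32660039 (MESP2) and 20381314 to 33424837 (UNCX). The first and the next principal component took 46.6% and 20.5% of the variance. Within the unsorted groups, replicate 3 stood apart, with a chi-square per gene of 51.35 to 70.51 against the other replicates of its group, which differed from each other by 8.37 to 10.28. Another 4 libraries stood apart by their keratinocyte genes, which summed to 1064 CPM in replicate 3 of the high MESP2 fraction, 1156 CPM in replicate 3 of the low MESP2 fraction, 1311 CPM in replicate 2 of the 120 h MESP2 fraction and 1444 CPM in replicate 2 of the UNCX fraction, against 9.32 to 67.7 CPM in the other 17.

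**Figure D1:**
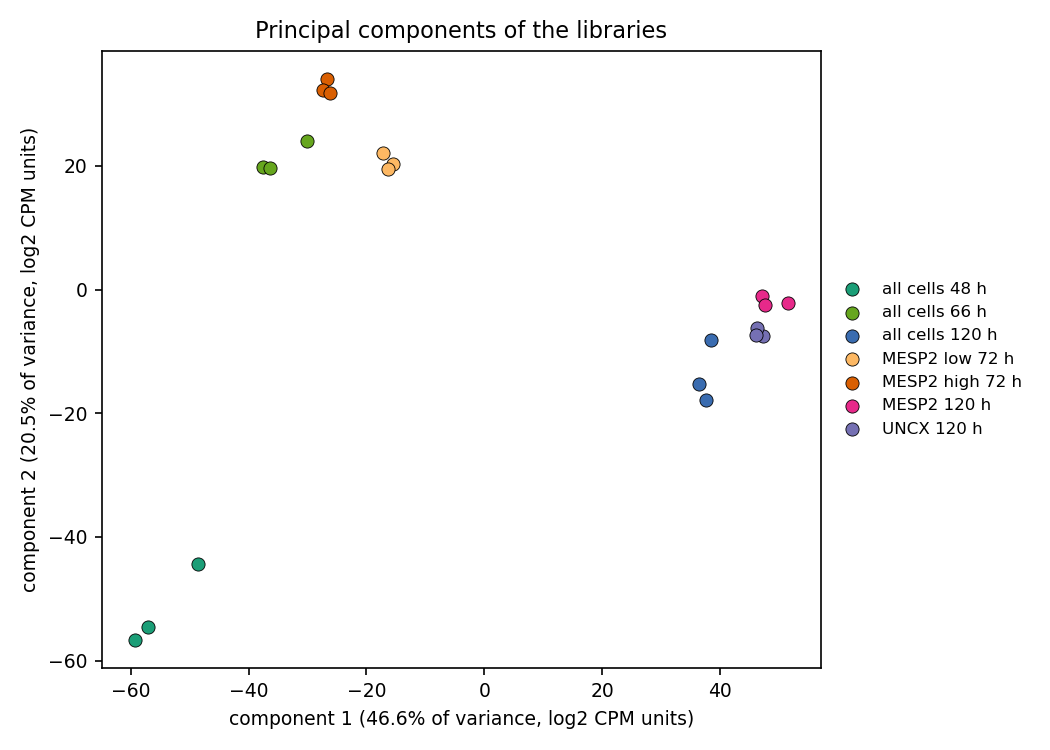
Principal components 1 and 2 of log2 CPM over 11594 genes, with a point for each of the 21 libraries coloured by group. The 48 h libraries lie between −59.3 and −48.5 on component 1 and the sorted 120 h libraries between 46 and 51.5.

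The comparison of 66 h with 48 h asked which genes changed as cells left the primitive streak state. MESP2 and genes of early somites appeared, and TBXT and WNT3A of the streak fell. MESP2 (GRCh38 chromosome 15, 89760591 to 89778754) went from 0.103 ± 0.130 CPM to 367 ± 42.8 CPM (mean ± SD, n = 3). The repressors RIPPLY1 and RIPPLY2 also appeared. RIPPLY1 (chromosome X, 106900063 to 106903335) went from 0.0909 ± 0.11 to 162 ± 50.0 CPM and RIPPLY2 (chromosome 6, 83853266 to 83857515) rose by a log2 change of 10.56 ± 0.36 (SE; adjusted p = 3.31e-13) to 386 ± 111 CPM. The 48 h libraries held 9 reads of MESP2 and 8 of RIPPLY1 in all, so no fold is given for them. MEOX1 (chromosome 17, 43640388 to 43661954), a homeobox factor of early somites, rose by 9.70 ± 0.31 (adjusted p = 9.25e-14) to 430 ± 92.0 CPM, and FOXC2, a forkhead factor of paraxial mesoderm, rose by 6.63 ± 0.21 to 438 ± 88.2 CPM. TBXT (chromosome 6, 166157656 to 166168700), the T-box factor of the primitive streak, changed by −6.13 ± 0.37 (adjusted p = 4.69e-10), from 746 ± 65.6 to 10.6 ± 0.635 CPM, and the Wnt ligand WNT3A changed by −6.67 ± 0.42. UNCX was near the floor at both times, with 0.0336 and 0.323 CPM. Of 13 genes of the primitive streak and nascent mesoderm, 8 were lower and 4 higher, the same counts adjusted over the list alone, with no call for the list (camera adjusted p = 0.061, and 0.493 with an estimated correlation). It was called without replicate 3 of the 48 h group (0.0457) or replicate 1 (0.0463) or 2 (0.0394) of the 66 h group. The list was also called with no count filter (0.0218), in a fit of only the compared libraries (0.0227) and with the offset for transcript length (0.0479). Its adjusted p ran from 0.0218 to 0.1 over the alternatives.

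Of the 12 determination front genes, 9 rose and 2 fell (camera adjusted p = 6.44e-07, and 0.0381 with an estimated correlation), the same counts as when adjusted over the list alone. Most of the 8 rostral somite genes are also in the front's list. Of the rostral genes, 7 rose and 1 fell (adjusted p = 1.76e-06, and 0.0194 with an estimated correlation), with the same counts adjusted over the list alone. The protocadherin PCDH8, a member of both, rose by 6.08 ± 0.37 to 1076 ± 60.6 CPM. Of the 8 caudal somite genes, 5 rose and none fell (adjusted p = 4.5e-05, and 0.0381 with an estimated correlation), and 7 rose adjusted over the list alone. Among these, the ephrin EFNB2 rose by 4.28 ± 0.10 and the Notch ligand DLL1 by 1.71 ± 0.35. Of 16 somite genes, 11 rose and 2 fell (adjusted p = 2.04e-07, and 0.0194 with an estimated correlation), or 11 and 3 adjusted over the list alone. The count that fell was 1 without replicate 2 of the 66 h group, and 1 without the third replicates. TCF15, needed for somites to form epithelium, rose by 5.99 ± 0.24 to 209 ± 18.4 CPM.

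Notch genes rose, with 10 of 15 higher and 0 lower, or 11 and 0 adjusted over the list alone (adjusted p = 6.44e-07). This list's adjusted p = 0.0592 with an estimated correlation, and 1 member was lower with a replicate block within each set of libraries. HES4 rose by 5.02 ± 0.25 and NRARP, a Notch feedback gene, by 3.35 ± 0.20. Wnt targets fell, with 11 of 14 lower and 3 higher, the same counts adjusted over the list alone (adjusted p = 6.44e-07, and 0.00515 with an estimated correlation). NOTUM changed by −4.24 ± 0.22 and SP5 by −3.41 ± 0.21, from 434 ± 16.6 to 40.8 ± 8.04 CPM. FGF targets were lower in 8 of 12 and higher in 2, the same counts adjusted over the list alone (adjusted p = 0.00162). That call's adjusted p = 0.269 with an estimated correlation. IL17RD, an FGF feedback gene, changed by −2.99 ± 0.23, while SPRY1, another, rose by 3.38 ± 0.25. Over 17024 genes, 2435 were higher and 2669 lower at 66 h (edgeR quasi-likelihood test). With a replicate block within each set of libraries 3847 were higher.

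The comparison of 120 h with 66 h asked what followed the segmentation front. MESP2, PCDH8 and TBX6 fell, and PAX3 and DMRT2 of the dermomyotome rose. PCDH8 (chromosome 13, 52842889 to 52848641) changed by −10.47 ± 0.48 (SE; adjusted p = 8.42e-12), from 1076 ± 60.6 to 0.770 ± 0.182 CPM, and MESP2 by −10.27 ± 0.56, to 0.299 ± 0.182 CPM. TBX6 (chromosome 16, 30085793 to 30091887), the T-box factor of presomitic mesoderm, changed by −7.81 ± 0.33, from 281 ± 15.9 to 1.25 ± 0.160 CPM. FMOD (chromosome 1, 203340628 to 203351758), which encodes the matrix proteoglycan fibromodulin, rose by 8.55 ± 0.36 (adjusted p = 3.51e-12), from 1.77 ± 0.0191 to 668 ± 49.3 CPM. MEOX2, a homeobox factor of somites, rose by 9.19 ± 0.45 to 95.6 ± 9.58 CPM, and IGFBP5, which binds insulin-like growth factors, rose by 6.50 ± 0.45 to 1564 ± 35.8 CPM. UNCX (chromosome 7, 1232907 to 1237318) rose by 3.61 ± 0.33 (adjusted p = 8.18e-08) to 4.05 ± 1.37 CPM.

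All 12 determination front genes fell (camera adjusted p = 2.02e-12, and 0.00751 with an estimated correlation), as did 12 of 14 genes of the posterior presomitic mesoderm, with 1 higher (adjusted p = 7.08e-11, and 0.00751 with an estimated correlation). Both gave these counts adjusted over the list alone. In the latter list DLL3, a Notch ligand, changed by −5.81 ± 0.19, from 1236 ± 140 to 22.0 ± 0.310 CPM. Of 13 genes of the primitive streak and nascent mesoderm, 10 fell and 0 rose, again also adjusted over the list alone (adjusted p = 1.09e-08). With an estimated correlation this list's adjusted p = 0.0509. The apelin receptor APLNR changed by −5.05 ± 0.32, from 4178 ± 732 to 126 ± 13.9 CPM. Wnt targets again fell, with 10 of 14 lower and 2 higher, and the same counts adjusted over the list alone (adjusted p = 0.00315, and 0.0376 with an estimated correlation). LEF1 changed by −1.83 ± 0.10 and NOTUM rose by 2.32 ± 0.21. Notch genes were lower in 10 of 15 and higher in 2, equal to the counts adjusted over the list alone (adjusted p = 0.000262). Their adjusted p = 0.175 with an estimated correlation. HES7, a gene of the segmentation clock, changed by −3.85 ± 0.28.

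Dermomyotome and muscle genes rose, 6 of 8 with 0 lower, also adjusted over the list alone (adjusted p = 1.65e-05, and 0.0181 with an estimated correlation), though the stricter count filter gave 0.0531, the highest of alternatives that ran from 1.8e-07. PAX3, a paired box factor of the dermomyotome, rose by 4.36 ± 0.25 to 321 ± 14.9 CPM, DMRT2 rose by 3.99 ± 0.16, and MYF6, a muscle regulatory factor, rose by 5.74 ± 0.37 to 8.65 ± 1.14 CPM. Cholesterol synthesis genes fell in 13 of 18 and rose in 0, the counts adjusted over the list alone being the same (adjusted p = 3.03e-05). That call's adjusted p = 0.0775 with an estimated correlation. CYP51A1 changed by −1.15 ± 0.18 and HMGCS1 by −0.88 ± 0.13. Among markers of other cell types, 5 of 6 intermediate mesoderm genes fell and 0 rose (adjusted p = 0.00149, and 0.0181 with an estimated correlation), or 5 and 1 adjusted over the list alone. With a replicate block within each set of libraries 1 rose. SALL1 changed by −2.86 ± 0.14. In all, 3113 genes were higher and 3238 lower at 120 h.

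Combining these 2 comparisons, 321 genes were highest at 66 h and 261 lowest there, each with at least 2-fold changes on both sides, and the stricter count filter gave 131 of the latter. Both comparisons use the 66 h libraries. In 20 simulations of unchanged groups the mean count was 0. A gene with no change would need a false call on both sides, so this does not measure chance among genes that do change. Independent lists of these sizes would share 61.7 and 94.7 genes. Part of the excess may come from the shared libraries, since 3 libraries could not be split. Besides MESP2, RIPPLY2, CER1 and PCDH8, the genes with the largest such changes included FGF18, a fibroblast growth factor, at 0.865 ± 0.437, 348 ± 78.0 and 11.9 ± 1.08 CPM at the 3 times, and RELN, which encodes the secreted protein reelin, at 1.68 ± 0.547, 205 ± 18.0 and 7.76 ± 2.26 CPM. MESP1, the paralogue of MESP2, was at 1.43 ± 0.388, 60.6 ± 3.10 and 1.02 ± 0.353 CPM. The histone gene HIST1H2BJ was at 3.06 ± 0.258, 120 ± 12.6 and 0.580 ± 0.246 CPM.

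**Figure D2:**
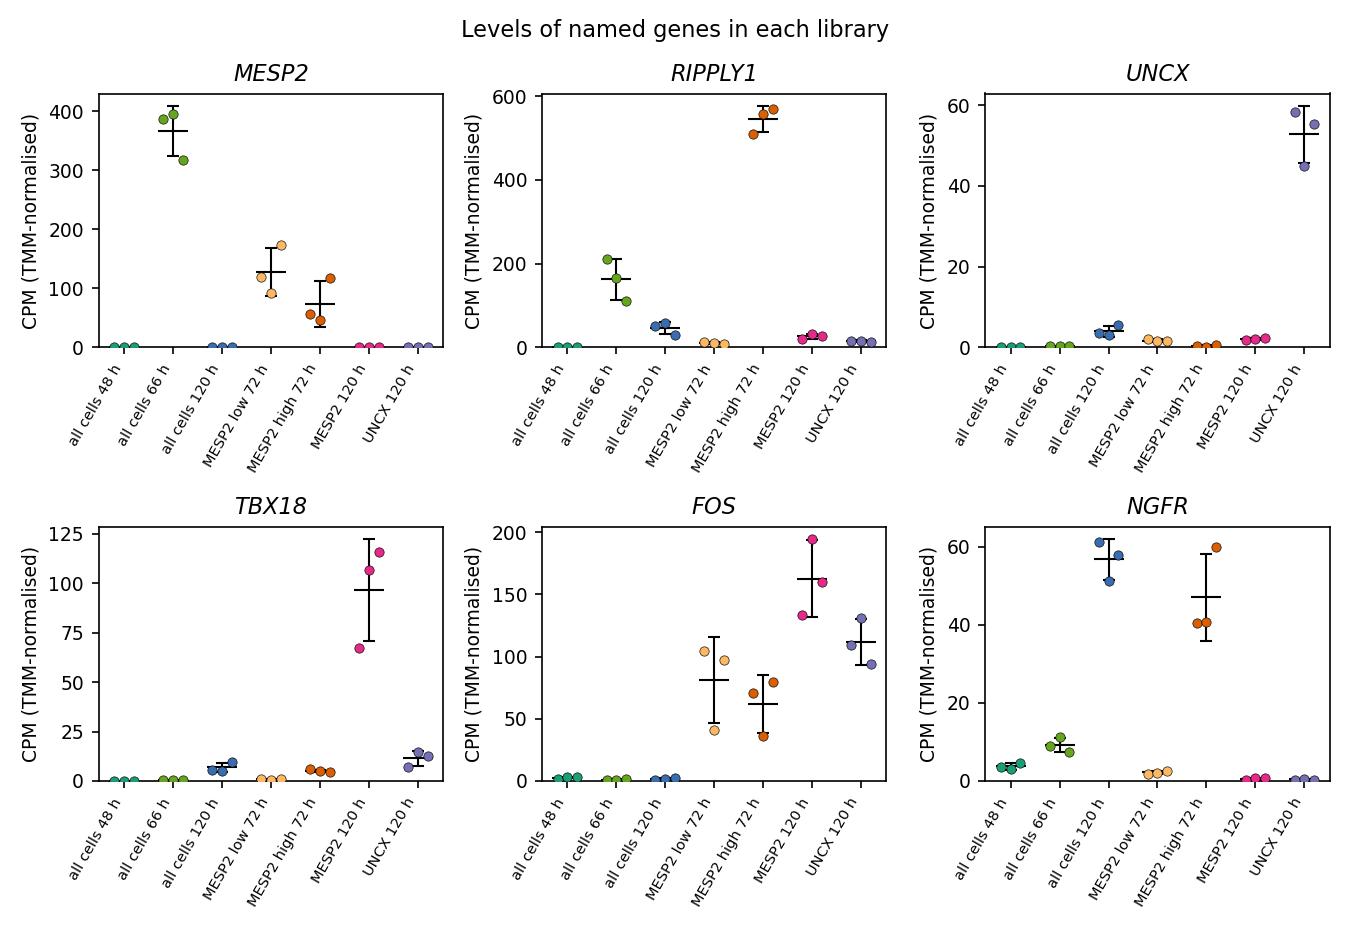
Levels of MESP2, RIPPLY1, UNCX, TBX18, FOS and NGFR in CPM (y axis, from 0) in each of the 7 groups (x axis), with a point per library, bars at the mean and error bars of 1 SD (n = 3). MESP2 peaks at 66 h at 367 CPM, and UNCX is at 52.8 CPM in the UNCX fraction and at most 4.05 CPM on average elsewhere.

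The comparison of the 72 h fractions asked what distinguished cells sorted for high from cells sorted for low MESP2. MESP2 mRNA itself was at 74.0 ± 38.8 CPM in the fraction labelled MESP2 high and 128 ± 41.4 CPM in the fraction labelled MESP2 low, a log2 change of −0.79 ± 0.33 (SE) that missed the threshold (adjusted p = 0.122). Directions below are therefore those of the labels. MESP2 was lower in the fraction labelled high in 3 of 3 same-numbered pairs, with a mean log2 ratio of −0.86 ± 0.28 (SD). It was called lower with a replicate block within each set of libraries (−0.86, adjusted p = 8.93e-05), with an offset for transcript length (−0.91, adjusted p = 0.0166), without the keratinocyte-containing libraries (−1.03, adjusted p = 0.00554) and without replicate 3 of the fraction labelled high (−1.30, adjusted p = 0.00806). Over all alternatives the change ran from −1.30 to −0.52 and the adjusted p from 8.93e-05 to 0.528.

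Genes that mark the rostral and caudal parts of somites differed between the fractions. RIPPLY1 was higher in the fraction labelled MESP2 high by 5.66 ± 0.30 (SE; adjusted p = 3.59e-10), at 546 ± 31.6 against 10.7 ± 1.69 CPM. TBX18 (chromosome 6, 84687351 to 84764519), a T-box factor of the rostral somite, was higher by 2.56 ± 0.34 (adjusted p = 2.15e-05), at 5.14 ± 0.658 against 0.867 ± 0.294 CPM. UNCX changed by −2.38 ± 0.34 (adjusted p = 4.83e-05), at 0.343 ± 0.178 against 1.71 ± 0.269 CPM. The keratins of simple epithelia KRT8 and KRT18 (chromosome 12, 52897187 to 52949954 and 52948871 to 52952901) changed by −3.95 ± 0.37 and −4.43 ± 0.39, with KRT8 at 189 ± 2.56 against 2927 ± 24.8 CPM. NODAL, a ligand of the transforming growth factor beta family, changed by −5.29 ± 0.32, and NPPB, which encodes a natriuretic peptide, by −7.09 ± 0.84, at 0.268 ± 0.116 against 34.6 ± 2.85 CPM. MESP1 changed by −2.48 ± 0.24, at 6.19 ± 1.61 against 34.2 ± 4.79 CPM. RIPPLY2, named here after its values were seen, was at 60.8 ± 12.7 against 131 ± 4.49 CPM.

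Of 8 rostral somite genes, 5 were higher and 1 lower (camera adjusted p = 0.000486, and 0.0373 with an estimated correlation), or 5 and 2 adjusted over the list alone. The count of lower genes was 2 with a replicate block within each set of libraries, and 2 without the keratinocyte-containing libraries. CER1, a secreted antagonist, was higher by 3.05 ± 0.32 and PCDH8 by 2.90 ± 0.32, at 2288 ± 349 against 306 ± 51.7 CPM. Of 8 caudal somite genes, 4 were lower and 0 higher, also adjusted over the list alone (adjusted p = 0.00344). Their adjusted p = 0.124 with an estimated correlation. SEMA3F, a semaphorin, changed by −1.35 ± 0.20 and EFNB2 by −0.58 ± 0.09. Genes of the posterior presomitic mesoderm were lower in 6 of 14 and higher in 2, or 10 and 2 adjusted over the list alone (adjusted p = 0.0158). Their adjusted p = 0.262 with an estimated correlation and 0.124 with the stricter filter, the highest of alternatives that ran from 0.00175. Of 16 somite genes 8 were higher and 2 lower, also adjusted over the list alone (adjusted p = 0.0323, and 0.337 with an estimated correlation), with EYA1 higher by 0.86 ± 0.11. That call was lost with the stricter filter (adjusted p = 0.051) and without replicate 3 of the fraction labelled high (0.0544) or replicate 2 of the fraction labelled low (0.0581), over a range of 0.00916 to 0.0581. The counts were 5 and 1 without replicate 1 of the fraction labelled high, and 1 was lower without its replicate 2 or without replicate 1 or 2 of the fraction labelled low. MSGN1, a factor of posterior presomitic mesoderm, changed by −2.73 ± 0.31, and TBX6 by −1.25 ± 0.23.

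Wnt targets were lower in 10 of 14 and higher in 3, the same counts adjusted over the list alone (adjusted p = 0.00135, and 0.0373 with an estimated correlation). The Wnt antagonist DKK1 changed by −3.43 ± 0.30, at 6.22 ± 3.13 against 69.1 ± 19.8 CPM, while another antagonist, WIF1, was higher by 4.24 ± 0.46. Retinoic acid genes were lower in 6 of 11 and higher in 1, or 7 and 1 adjusted over the list alone (adjusted p = 0.0051). The adjusted p = 0.262 with an estimated correlation, and 2 were higher with a replicate block within each set of libraries. RARG, a retinoic acid receptor, changed by −1.50 ± 0.14 and CRABP2, which binds retinoic acid, by −1.48 ± 0.25. Of 21 Eph receptors and ephrins, 10 were lower and 2 higher, also adjusted over the list alone (adjusted p = 0.0228). With an estimated correlation the adjusted p = 0.0633. EPHB3 changed by −2.63 ± 0.21, and EPHA4, a receptor of rostral somite cells, was higher by 1.62 ± 0.11.

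Markers of endoderm and of lateral plate and heart were lower in the fraction labelled MESP2 high. Of 5 endoderm genes 4 were lower and 0 higher (adjusted p = 0.000486, and 0.0373 with an estimated correlation), or 5 and 0 adjusted over the list alone. CLDN6, a claudin, changed by −2.05 ± 0.19. Of 8 genes of lateral plate and heart, 5 were lower and 1 higher (adjusted p = 0.00145, and 0.0373 with an estimated correlation), or 7 and 1 adjusted over the list alone, and 0 were higher without the keratinocyte-containing libraries. MYL7, a myosin light chain of the heart, changed by −4.48 ± 0.62 and GATA6 by −2.32 ± 0.27. Of 20 proliferation genes, 6 were higher and 0 lower, or 7 and 0 adjusted over the list alone (adjusted p = 0.00894). That adjusted p = 0.526 with an estimated correlation, and 3 were higher without replicate 1 or 2 of the fraction labelled high or replicate 3 of the fraction labelled low, against 12 with a replicate block within each set of libraries. In all, 1172 genes were higher and 1839 lower in the fraction labelled MESP2 high. A replicate block within each set of libraries gave 2406 and 2825.

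The comparison of the 120 h fractions asked what distinguished cells enriched for MESP2 from cells enriched for UNCX. UNCX, for which that fraction is named, was at 2.04 ± 0.266 CPM in the MESP2 fraction and 52.8 ± 7.04 CPM in the UNCX fraction (−4.70 ± 0.29, SE; adjusted p = 3.99e-08). TBX18 was higher in the MESP2 fraction by 3.08 ± 0.29 (adjusted p = 1.35e-05), at 96.6 ± 25.8 against 11.4 ± 3.80 CPM. MESP2 was near the floor in both, at 0.563 ± 0.537 and 0.434 ± 0.368 CPM (adjusted p = 0.948). The growth factor FGF8 (chromosome 10, 101770130 to 101780369) changed by −2.55 ± 0.18 (adjusted p = 3.24e-07), at 2.31 ± 0.286 against 13.4 ± 2.40 CPM, and PLXNA2, a semaphorin receptor, by −2.03 ± 0.12, at 39.2 ± 6.76 against 161 ± 9.35 CPM. CRABP1, which binds retinoic acid, was higher in the MESP2 fraction by 2.48 ± 0.42, SNAI2, a zinc finger factor of mesenchyme, by 1.22 ± 0.15, and the receptor EPHB1 by 1.17 ± 0.15. DLL1 (chromosome 6, 170282206 to 170306565) changed by −1.67 ± 0.36 (adjusted p = 0.0126), at 30.6 ± 16.3 against 96.4 ± 13.3 CPM. Its call was lost in a fit of only the compared libraries (adjusted p = 0.0983), the highest of all alternatives, which ran from 9.41e-05.

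Of 8 rostral somite genes, 3 were higher and 0 lower (camera adjusted p = 0.000308), or 4 and 0 adjusted over the list alone. The list's adjusted p = 0.0544 with an estimated correlation, and only 1 was higher without replicate 3 of the MESP2 fraction, without replicate 3 of the UNCX fraction or without the keratinocyte-containing libraries. Of 8 caudal somite genes, 1 was higher (LFNG, 0.97 ± 0.18) and 2 lower (UNCX and DLL1), with no call for the list (adjusted p = 0.565). LFNG lost its call in a fit of only the compared libraries (adjusted p = 0.0983), where its alternatives ran from 1.18e-05. HOX genes of groups 1 to 4 were higher in 4 of 12 and lower in 0, or 6 and 0 adjusted over the list alone (adjusted p = 1.26e-05). Their adjusted p = 0.131 with an estimated correlation, and the count of 4 became 7 without replicate 1 of the MESP2 fraction, 2 without replicate 1 of the UNCX fraction and 8 with a replicate block within each set of libraries. HOXD3 was higher by 1.50 ± 0.24, at 20.4 ± 4.41 against 7.20 ± 0.539 CPM.

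Markers of lateral plate and heart and of intermediate mesoderm were higher in the MESP2 fraction beside the rostral genes. Of 8 genes of lateral plate and heart 3 were higher and 0 lower, or 5 and 0 adjusted over the list alone (adjusted p = 0.00322), and of 6 intermediate mesoderm genes 2 were higher and 0 lower, or 3 and 0 adjusted over the list alone (adjusted p = 0.0051). Both lists had an adjusted p = 0.0544 with an estimated correlation. The ligand gene BMP4 was higher by 1.21 ± 0.23 and SALL1 by 0.93 ± 0.13, and a fit of only the compared libraries ended both calls (adjusted p = 0.134 in a range from 3.32e-05, and 0.0694 in a range from 2.25e-09) and left 0 genes of either list called. The count for lateral plate and heart was 1 without replicate 1 of the MESP2 fraction or any replicate of the UNCX fraction, and 5 with a replicate block within each set of libraries. That for intermediate mesoderm was 1 without replicate 2 of the MESP2 fraction, any replicate of the UNCX fraction or the keratinocyte-containing libraries.

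Cholesterol synthesis genes were lower in the MESP2 fraction in 9 of 18 and higher in 0, or 13 and 0 adjusted over the list alone (adjusted p = 2.22e-12, and 0.0206 with an estimated correlation). DHCR7 changed by −0.57 ± 0.08 and HMGCS1 by −0.66 ± 0.13, and both lost their call in a fit of only the compared libraries (adjusted p = 0.0598 in a range from 2.18e-10, and 0.0848 in a range from 1.56e-05). Proliferation genes were lower in 10 of 20 and higher in 0, or 14 and 0 adjusted over the list alone (adjusted p = 1.37e-11). Their adjusted p = 0.131 with an estimated correlation. The lists of lateral plate and heart (adjusted p = 0.00322) and of intermediate mesoderm (adjusted p = 0.0051) were higher in the same fraction, each with an adjusted p = 0.0544 with an estimated correlation. Both counts moved with single libraries. The cholesterol count was 4 without replicate 2 of the MESP2 fraction, 3 without its replicate 3, 3 without replicate 1 or 3 of the UNCX fraction, 4 without the keratinocyte-containing libraries and 17 with a replicate block within each set of libraries. The proliferation count was 0 without replicate 2 or 3 of the MESP2 fraction, 1 without replicate 1 and 4 without replicate 3 of the UNCX fraction, and 0 without the keratinocyte-containing libraries.

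In all, 435 genes were higher and 380 lower in the MESP2 fraction. These counts were 684 and 766 without replicate 1 of the MESP2 fraction, 172 and 100 without its replicate 2, 214 and 95 without its replicate 3, 131 and 91 without replicate 1 of the UNCX fraction, and 142 and 113 without its replicate 3. They were 37 and 29 in a fit of only the compared libraries, 160 and 107 without the keratinocyte-containing libraries, and 672 and 790 by the DESeq2 test. A replicate block within each set of libraries gave 1428 and 1638 genes. Replicate 1 of the MESP2 fraction stood apart in ANKRD1, a stretch-responsive gene: its change of 2.51 ± 0.62 (adjusted p = 0.0259) was 1.05 (adjusted p = 0.192) without that library, and the call was also lost without replicate 1 (adjusted p = 0.119), 2 (0.0673) or 3 (0.11) of the UNCX fraction, over a range of 0.00704 to 0.192 in all alternatives.

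Across the 17024 genes, the fraction differences at 72 h and 120 h had a Pearson correlation of −0.068 and a Spearman correlation of −0.074, where genes are not independent replicates and no library is shared. The former was −0.001 without replicate 1 of the 120 h MESP2 fraction and −0.104 with the stricter count filter. Genes higher in both comparisons numbered 108 and genes lower in both 53, where independent lists would share 29.9 and 41. Genes called in opposite directions numbered 198, against 73.2. Ranked by the smaller of the 2 changes, TBX18 led the genes higher in both and UNCX those lower in both, and HOXD3 was higher in both, by 1.41 ± 0.23 and 1.50 ± 0.24. With the 72 h labels turned, these genes would be among those in opposite directions, the 198 would be the genes called in the same direction, and both correlations would change sign.

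The fractions compared are unlike, high against low MESP2 at 72 h and MESP2 against UNCX at 120 h. A change with time therefore cannot be told apart from unlike gates, here and in the correlation above. A test of the difference between the 72 h and 120 h fraction differences called 1044 genes as more positive at 72 h and 1542 as more negative. With a replicate block within each set of libraries these were 2444 and 2585, and with the 72 h labels turned they were 1180 and 870. RIPPLY1 differed by 4.83 and KRT8 by −4.85 in log2 units, the latter −4.10 without replicate 1 of the 120 h MESP2 fraction. Lateral plate and heart genes were more negative at 72 h in 5 of 8 and more positive in 0, or 7 and 0 adjusted over the list alone (camera adjusted p = 3.79e-05, and 0.0271 with an estimated correlation), and endoderm genes in 3 of 5 and 0, also adjusted over the list alone (adjusted p = 0.000264, and 0.0322 with an estimated correlation). Wnt targets were more negative in 8 of 14 and more positive in 3, or 9 and 3 adjusted over the list alone (adjusted p = 0.000376, and 0.0322 with an estimated correlation), with 1 more positive without the keratinocyte-containing libraries. DKK1 differed by −4.17 and RNF43, a Wnt feedback gene, by −2.72. These lists, DKK1 and RNF43 were not tested with the 72 h labels turned, so their directions hold for the labels as given.

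The comparison of the 120 h fractions with unsorted cells of that time asked what set sorted cells apart. FOS and EGR1 of the immediate early genes were higher and RARB and CRABP2 of the retinoic acid genes lower in sorted cells. FOS (chromosome 14, 75278774 to 75282230), an immediate early factor, was at 163 ± 30.7 CPM in the MESP2 fraction, 112 ± 18.5 CPM in the UNCX fraction and 1.75 ± 0.562 CPM in unsorted cells, a log2 change of 6.27 ± 0.43 (SE; adjusted p = 9.11e-09). EGR1, another, was higher by 4.67 ± 0.32 (adjusted p = 7.68e-09). NGFR (chromosome 17, 49495293 to 49515017), a neurotrophin receptor, changed by −6.95 ± 0.25 (adjusted p = 2.17e-12), at 0.612 ± 0.273 and 0.384 ± 0.223 against 56.8 ± 5.20 CPM. HOXB1 (chromosome 17, 48528526 to 48531001) changed by −4.27 ± 0.15, at 3.62 ± 0.960 and 1.68 ± 0.462 against 47.2 ± 6.08 CPM, and the transporter gene SLC6A12 by −6.19 ± 0.18. FOXC2 was higher by 1.77 ± 0.15 and FOXC1 by 1.28 ± 0.17. TBX18 was higher by 2.28 ± 0.27 and UNCX by 1.36 ± 0.23, and MESP2 did not pass the test (0.51 ± 0.83, adjusted p = 0.67). These changes are means over both fractions, so a single fraction can carry them. UNCX had a higher mean than unsorted cells only in the UNCX fraction, and a lower mean in the MESP2 fraction.

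Of 17 immediate early and heat shock genes, 10 were higher and 3 lower, or 11 and 3 adjusted over the list alone (camera adjusted p = 0.00105). Their adjusted p = 0.481 with an estimated correlation. FOSB was higher by 4.49 ± 0.61 and EGR2 by 3.98 ± 0.48. Of 11 retinoic acid genes, 9 were lower and 0 higher, the counts adjusted over the list alone being the same (adjusted p = 5.5e-06). Here the adjusted p = 0.266 with an estimated correlation. RARB changed by −3.45 ± 0.37 (adjusted p = 1.88e-06), CRABP2 by −1.77 ± 0.20 and STRA6, a retinol transporter, by −1.67 ± 0.15. CRABP1, another of the 9, was lower mainly in the UNCX fraction. It was at 27.2 and 4.86 CPM in the MESP2 and UNCX fractions against 28.9 CPM in unsorted cells. Matrix genes and integrins were higher in 10 of 19 and lower in 0, or 12 and 0 adjusted over the list alone (adjusted p = 0.000538). This adjusted p = 0.481 with an estimated correlation. The collagens COL4A2 and COL5A1 were higher by 1.21 ± 0.12 and 1.12 ± 0.09. Proliferation genes were lower in 12 of 20 and higher in 0, or 13 and 0 adjusted over the list alone (adjusted p = 0.000316). The adjusted p = 0.495 with an estimated correlation, and the count was 6 without replicate 2 of the unsorted cells and 7 without replicate 2 or 3 of the MESP2 fraction, replicate 3 of the UNCX fraction or the keratinocyte-containing libraries. CCNB1, a mitotic cyclin, changed by −0.64 ± 0.11.

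No list of markers of another cell type was called in this comparison, except endothelial and blood genes when no count filter was used. Of 7 neural crest genes 3 were higher and 1 lower, the lower being NGFR (adjusted p = 0.552), and of 10 endothelial and blood genes 5 were lower and 0 higher (adjusted p = 0.076, and 0.0268 with no count filter, over a range of 0.0268 to 0.204), with the receptor KDR at −1.96 ± 0.21. TUBB3, a neuronal tubulin, changed by −2.60 ± 0.13, at 37.7 ± 11.7 and 51.2 ± 5.24 against 267 ± 9.68 CPM. The epithelial genes LAMB3 and SERPINB5 were higher in sorted cells, with a change of 4.62 ± 1.26 (adjusted p = 0.00975) for LAMB3, and moved with the keratinocyte-containing libraries. Without these libraries LAMB3 was at 3.19 (adjusted p = 0.00237). It lost its call without replicate 2 of the unsorted cells (adjusted p = 0.0513), with 3.46e-05 to 0.0513 over the alternatives. SERPINB5 had 2 reads in the unsorted libraries and lost its call without replicate 1 (adjusted p = 0.125), 2 (0.147) or 3 (0.102) of these and without replicate 2 of the MESP2 (0.117) or UNCX (0.131) fraction, with 0.0219 to 0.147 over the alternatives. In all, 2724 genes were higher and 2825 lower in sorted cells. Leaving out replicate 1 or 2 of the unsorted cells gave 1783 and 1803 or 1695 and 1717. On component 3 (9.8% of the variance) the sorted 120 h libraries lay at −22.7 to −11.22. The unsorted replicates 1, 2 and 3 of that time lay at 42.59, 39.95 and 21.19. Replicate 3 was also the lowest unsorted library there at 48 h (−24.22) and at 66 h (0.69), so this axis does not follow the sort alone.

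**Figure D3:**
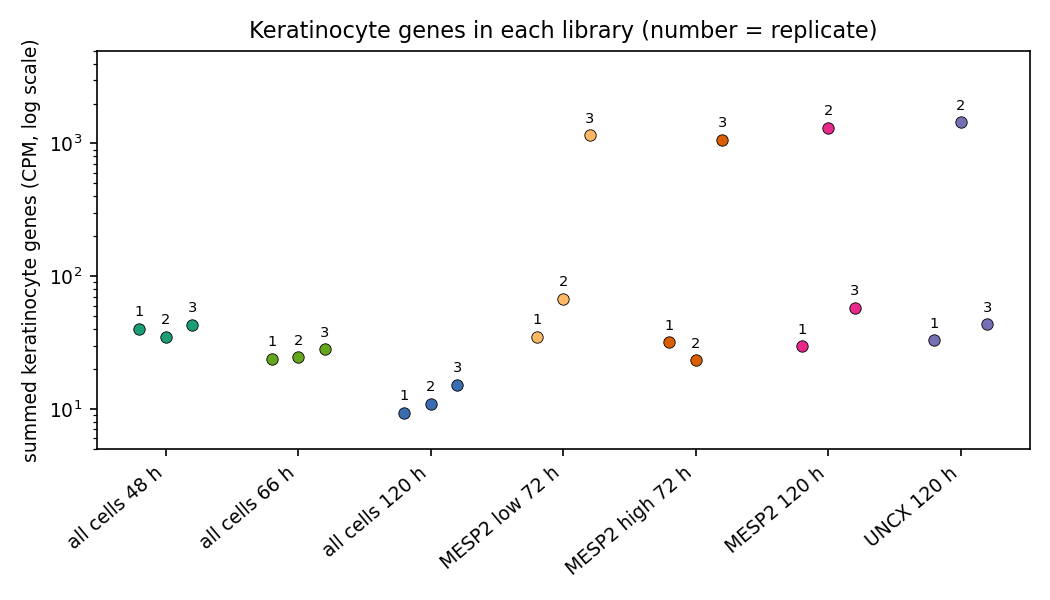
Summed keratinocyte genes in CPM (y axis, log scale) in each library, with groups on the x axis and numbers for replicates. Replicate 3 of both 72 h fractions and replicate 2 of both 120 h fractions lie between 1064 and 1444 CPM and the other 17 between 9.32 and 67.7 CPM.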

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

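The tests of swapped labels, of sort handling for the immediate early genes, of cells left out by the gates, of sequencing depth, of epidermal cells in the culture, and of splits that part same-numbered pairs were chosen after the results they measure had been seen.

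A test of the difference itself set the 72 h fraction difference (MESP2 high against low) against that at 120 h (MESP2 against UNCX). It called 1044 genes as more positive at 72 h and 1542 as more negative. The gates differ as well as the times, so a change with time cannot be told apart from unlike gates. The real grouping gave 2586 genes in all and the highest of the other splits gave 2050, so that 1 of 100 splits was as large. Mixing the labels within a time removes the fraction difference at that time. These splits therefore do not measure chance for a difference between the times. The 32 splits that part all same-numbered pairs at both times gave the same real and highest other counts, with 1 of 32 as large. The split with 2050 genes turned all 120 h labels, and those of the 32 that kept the 72 h grouping and mixed that at 120 h called 1160 to 1622, which points to structure from the 72 h difference. With the 72 h labels turned, the test called 1180 genes as more positive and 870 as more negative, UNCX differed by 7.08, RIPPLY1 by −6.49 and NPPB by 3.65, so the values here hold for the labels as given. Among the genes named below, SLCO4A1 (−1.22, adjusted p = 0.103), TNC (1.61, 0.393), ACTC1 (0.938, 0.401) and NDUFA6 (−0.288, 0.979) had no call with the labels turned. Among genes more positive at 72 h, RIPPLY1 differed by 4.83 in log2 units, SLCO4A1 by 4.64, HHIP by 4.61, CEMIP by 4.58, PDE1C by 4.27, CD6 by 4.20, ADAMTSL1 by 3.97, NGFR by 3.75 and UNCX by 2.32. Among genes more negative at 72 h, NPPB differed by −10.52, NDUFA6 by −9.09, ANKRD1 by −8.06, TNC by −6.52, ACTC1 by −5.46, KRT18 by −5.34, FAM84B by −5.23 and KRT8 by −4.85. Without replicate 1 of the 120 h MESP2 fraction the values were −9.05 for NPPB, −6.60 for ANKRD1, −4.50 for TNC, −4.41 for ACTC1, −4.44 for KRT18 and −4.10 for KRT8. ANKRD1 was at −8.83 without replicate 1 of the fraction labelled MESP2 high, and CD6 at 2.92 without replicate 2 of the UNCX fraction. NDUFA6 lost its call without replicate 1 of the fraction labelled MESP2 high (−8.64, adjusted p = 0.0508), without replicate 3 of the fraction labelled MESP2 low (−4.12, adjusted p = 0.349) and without the keratinocyte-containing libraries (−5.71, adjusted p = 0.219), over a range of 0.000319 to 0.349. Its value was −9.74 without replicate 3 of the fraction labelled high and −9.68 without replicate 1 of the fraction labelled low. Outside the comparisons, transcripts matched to no gene held up to 3.02% of a library's reads.

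MESP2 mRNA was lower in the fraction labelled MESP2 high than in the fraction labelled MESP2 low in 3 of 3 same-numbered pairs. MESP2 reads counted to the paralogue MESP1 are argued against by the summed counts of both genes, which were lower too. The mean log2 ratio of the sum was −1.09 ± 0.3 (SD). MESP1 reads counted to MESP2 stay open, since MESP1 alone was lower, at −2.49 ± 0.26, and would lower both MESP2 and the sum. A fraction labelled high that lay further along the time course stays open as a small lead. As a shift of all genes that change from 66 h to 120 h it is argued against. The median fraction difference of genes higher at 120 h than at 66 h minus that of genes lower at 120 h was −0.1, −0.19 and −0.22 in the pairs (mean −0.17 ± 0.07, SD). That set need not move in a lead shorter than the time from 66 h to 120 h. Somite genes were higher (camera adjusted p = 0.0323, and 0.337 with an estimated correlation). Posterior presomitic mesoderm genes were lower (camera adjusted p = 0.0158, and 0.262 with an estimated correlation). Both go with such a lead. Swapped labels stay open, since UNCX at −2.38 and the 5 rostral genes higher in the fraction labelled high go against a swap, while lower MESP2, MESP1 and RIPPLY2 are what a swap could give. The state the sort was meant to separate, with a reporter that might outlast the mRNA, was not tested, because the labels describe no reporter.

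As the mean of both fractions, sorted cells at 120 h had 10 immediate early genes higher and 9 retinoic acid genes lower than all cells of that time. Handling during the sort is a candidate explanation for the immediate early genes: in all 6 libraries of the 72 h fractions, 6 of the 10 lay above every unsorted library of 66 h and 120 h, but only 3 also above those of 48 h, so the stage stays open for the others. FOS was at 62.0 and 81.2 CPM and EGR1 at 425 and 254 CPM in the fractions labelled MESP2 high and low, against 1.06 and 5.27 CPM in unsorted cells at 66 h and 2.79 and 52.2 CPM at 48 h, while EGR2 was at 1.73 and 0.926 CPM in these fractions against 6.34 CPM at 48 h. For the retinoic acid genes, handling cannot be told apart from a difference between the cells, since only 4 of the 9 had a lower mean in the 72 h fractions than in unsorted cells at 66 h and the ages differ. Cells of another type left out by both gates cannot be told apart either: neither the neural nor the neural crest list was called (lowest adjusted p = 0.552), but NGFR and TUBB3 were lower in sorted cells, and the lists do not cover every type a culture may hold.

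Keratinocyte genes stood out in replicate 3 of both 72 h fractions and replicate 2 of both 120 h fractions, with KRT5 at 186 to 262 CPM against at most 0.683 CPM in the other 17 libraries, KRT6A at 206 to 275 against 0.312, KRT14 at 131 to 180 against 0.526 and KRT16 at 127 to 166 against 0.207. Lower sequencing depth is argued against, since each of the 4 libraries held 11499 to 17504 reads of KRT5, KRT14, KRT6A and KRT17 and no other library more than 91, a ratio of at least 126.4. RNA or reads of a keratinocyte-containing sample are a candidate source: 14 of 16 keratinocyte genes not looked at before were higher in each of the 4 than in all others, and the ratios between genes varied over the 4 with a median SD of 0.117 (log2). Of the 26 genes of that list, 6 also reached 5 CPM in another library, and whether the MESP2 and UNCX gates would leave such cells out is not given in the sources used here. Epidermal cells arising in the culture cannot be told apart, as the summed levels lay within 1.36-fold of each other, and the design holds no group of such cells.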

How the results depend on the processing

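The fits without the keratinocyte-containing libraries, without the outlying unsorted libraries and with a replicate block within each set of libraries were chosen after seeing the data.

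Counted per comparison, DESeq2 size factors left the direction and call of 644 named genes as they were. The DESeq2 test did so for 639 and took the call from 2, a replicate block for 642 with 2 lost, and the offset for transcript length for 618 with 24 lost, 1 gained and 1 reversed. No count filter kept 630 and lost 14. The stricter filter kept 592 and lost 0 of the named genes that it left in, and the others were removed and so not tested. Of the list tests, no count filter left 172 as they were and added a call to 26, and the stricter filter left 172 as they were, added 10 calls and ended 10. The reversed gene was HOXB6 in 120 h against 66 h, at −0.25 (adjusted p = 0.504) with that offset against 1.39, where its adjusted p ran from 5.55e-06 to 0.504. A fit of only the compared libraries kept 564 and lost 72, leaving out 1 library kept 4464 and lost 401 over all genes and libraries with 1 gained, leaving out the keratinocyte-containing libraries kept 344 and lost 52 with 1 gained, and leaving out the outlying unsorted libraries kept 349 and lost 21, all 4 with fewer samples. For the MESP2 against the UNCX fraction at 120 h, with 435 genes higher and 380 lower, the DESeq2 test called 672 and 790, a fit of only those libraries 37 and 29, and a fit without the keratinocyte-containing libraries 160 and 107. The stricter filter, which tests fewer genes, gave 131 genes lowest at 66 h in place of 261 and a correlation between the fraction differences of −0.104 in place of −0.068. The plain replicate block moved no count of a comparison by over 1.5 times, with 2643 and 2822 genes for 66 h against 48 h and 522 and 532 for the 120 h fractions. The replicate block within each set of libraries called 3847 genes higher at 66 h than at 48 h, 2406 and 2825 between the 72 h fractions, 1428 and 1638 between the 120 h fractions and 2444 and 2585 in the difference of these. It moved no other total of called genes in a comparison by over 1.5 times, but moved 107 counts within lists, and kept 519 named genes with 1 gained and 0 lost. Unsorted and sorted libraries at 120 h share only a number, and a block gave 3046 and 3103 genes there. The cause was not tested, apart from fewer genes or samples by construction.

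Without 1 library at a time, the counts were 1945 to 2792 higher and 2168 to 2626 lower for 66 h against 48 h, 2527 to 2933 and 2743 to 3318 for 120 h against 66 h, 875 to 1038 and 1457 to 1708 for the 72 h fractions, 131 to 684 and 91 to 766 for the 120 h fractions, and 1695 to 2737 and 1717 to 3141 for sorted against all cells. They were 733 to 1172 and 1226 to 1596 for the difference of the fraction differences, 301 to 327 for genes highest and 224 to 256 for genes lowest at 66 h. The correlation of the fraction differences ran from −0.081 to −0.001, the latter without replicate 1 of the 120 h MESP2 fraction. For the 120 h fractions the lowest counts were those without replicate 1 of the UNCX fraction and the highest those without replicate 1 of the MESP2 fraction, and for sorted against all cells the lowest were without replicate 2 of the unsorted cells. At 15685113 to 38250175 reads per library, simulated 2-fold changes were recovered at 53.1 to 71%, so a gene without a call is not shown to be unchanged.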

Other observations

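The tests here were chosen before the results they measure were seen, except the comparisons of splits by same-numbered pairs, though the list of YAP and TEAD targets was written after ANKRD1, CYR61 and CTGF had been seen.

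The fraction labelled MESP2 high at 72 h had lower levels of targets of YAP and TEAD, which carry signals of cell spreading and tension into the nucleus. CYR61 changed by −2.52 ± 0.19 (SE) and CTGF by −2.65 ± 0.33 against the fraction labelled MESP2 low. Of 19 other targets, 13 were lower and 0 higher (camera adjusted p = 6.74e-11, and 0.00258 with an estimated correlation). Among them AXL, a receptor tyrosine kinase, changed by −2.77 ± 0.19, at 11.9 ± 1.56 against 82.0 ± 10.8 CPM, AMOTL2, which binds YAP, by −2.18 ± 0.23, at 28.5 ± 8.68 against 129 ± 34.1 CPM, and the kinase gene NUAK2 by −1.88 ± 0.15. In the MESP2 fraction against the UNCX fraction at 120 h, 1 of the 19 was higher and 0 lower (adjusted p = 0.316). A hypothesis is that YAP and TEAD activity may be lower in the cells labelled MESP2 high. Cells of other types in the fraction labelled low, where markers of endoderm and of lateral plate and heart were higher, stay open as another source of these genes.

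Single receptors of the Eph family, which separate cells at somite boundaries, differed with time and with the sort, while their list as a whole was not called in either comparison except under 2 alternatives. Of 21 Eph receptors and ephrins, 9 were higher and 4 lower at 120 h than at 66 h, the same counts adjusted over the list alone (camera adjusted p = 0.108). The list was called with the offset for transcript length (adjusted p = 0.0395) and with no count filter (adjusted p = 0.0454), over a range of 0.0395 to 0.136. EPHA3 rose by 4.32 ± 0.33 (SE) and EPHB2 by 3.57 ± 0.15, from 7.40 ± 0.2 to 87.7 ± 3.68 CPM, and EPHB1 changed by −1.96 ± 0.16. In sorted against all cells at 120 h, 4 were higher and 7 lower, or 4 and 8 adjusted over the list alone (adjusted p = 0.139). EPHB1 was higher by 2.78 ± 0.15, at 67.2 ± 13.1 and 29.8 ± 4.95 CPM in the MESP2 and UNCX fractions against 6.51 ± 0.531 CPM, while EPHB2 changed by −1.69 ± 0.11 and EPHB3 by −2.45 ± 0.16.

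Other splits of the same libraries were also fitted. For 66 h against 48 h the real grouping called 5104 genes and the highest other split 3, for 120 h against 66 h 6351 and 0, for the 72 h fractions 3011 and 0, and for the 120 h fractions 815 and 27. In each of these 4 comparisons 1 of 10 splits, the real one, was as large, and 10 splits are too few for a share under 0.05. The 3 other splits that part all 3 same-numbered pairs called 0 genes in each comparison by edgeR, and the splits that called 3 and 27 genes part only 1 pair. For sorted against all cells at 120 h the splits merged the MESP2 and UNCX libraries into a single group. In that fit the real grouping of the 9 libraries called 5178 genes, where the comparison itself called 5549. The highest other split called 1769, with 1 of 84 as large, a share that takes the 6 sorted libraries as independent. Same-numbered MESP2 and UNCX libraries were read as pairs, so this share does not exclude chance. Only 10 splits keep same-numbered sorted libraries together, which is too few for a share under 0.05, and the highest other of these called 0 genes by edgeR. Genes highest at 66 h numbered 321, with up to 1047 in another split and 5 of 100 as large. The 4 others as large each put all 48 h or all 120 h libraries in the place of those at 66 h, which points to structure from differences between the times, so these splits do not measure chance for this count. For the correlation between the fraction differences, −0.068, 36 of 100 splits were as large and the highest other was 0.637. Mixing the labels within a time removes the fraction difference at that time. These splits therefore do not measure chance for the correlation, and chance cannot be excluded for it.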
